A study of Mus musculus with 4 samples.

How the data were processed

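Open chromatin was profiled in the dentate gyrus of mice around 9 weeks old by FAIRE-seq (formaldehyde-assisted isolation of regulatory elements). In this assay fixed tissue is sonicated and extracted with phenol and chloroform, DNA that carries few nucleosomes stays in the aqueous phase, and that DNA is sequenced. Single-end Illumina libraries were made from 4 samples, 2 titled WT and 2 titled Mbd1 KO. Bowtie, SAMtools and MACS2 and the mouse build mm9 are named in the submitters' processing notes, without versions; thresholds, read filters and any input control are not given in the sources used here. The deposited files hold 1 list of peak summits per library, so peaks were not pooled across libraries. Each summit is 1 base wide and carries a score. The score deposited by the authors was taken as the −log10 p or q value that MACS2 usually writes in such a list; every value lies above 1.30, the −log10 of 0.05, and whether it is p or q is not given in the sources used here. Read depth and peak widths are not known from these lists, so no counting interval on the signal could be computed, and a longer list may come from more reads, from a better enrichment or from more open sites. Scores were used only to rank summits within a list or to filter summits. The filter, a score of at least 10, put the same cut on all 4 lists. With read depth unknown, differences in the counts above that cut may also come from depth.

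The labels conflict. The title and the source name of each sample name the same group, but the genotype field calls the library titled WT 1 a knockout and the library titled Mbd1 KO 2 a wild type. Groups were taken from the titles, and summit numbers, spacing, pair-only regions, overlap, chromosome shares and distances were also compared with the groups of the genotype field, which part the 4 libraries exactly as the replicate numbers do. Only the libraries titled WT 2 and Mbd1 KO 1 carry labels that agree. No library was assigned to a group from its data. The labels do not say whether the libraries of a group came from separate animals, so differences between them may be technical.

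Positions are given 1-based in mm9. Summits on chromosome 7 reached position 152520671, past the last gene end at 145324059 in the GRCm38 gene table at hand, so that table was not used for positions. No mm9 gene annotation or sequence was used here. The planned analyses of promoters, of gene lists, of base composition and of the Mbd1 gene itself were therefore not run, and regions are named by coordinates.

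Summits of any library within 250 bp of the next were joined to 1 region, and a region was counted as called in a library that had a summit in it. Overlap between libraries was measured with the Jaccard index, the regions called in both divided by the regions called in either. Counts of regions called in only 1 pair of libraries were compared across the 3 ways of parting 4 libraries into 2 and 2. Values per library were compared with an exact two-sided permutation test of the group labels, which with 2 libraries against 2 cannot give a p below 0.33. Chromosome shares were compared with Fisher's exact test over regions with Benjamini-Hochberg adjustment, and with 100000 permutations of the class labels; regions are not replicates, so those p-values describe these libraries only. The regions named in each direction were fixed before the data were examined as the 5 called in both libraries of one titled group and neither of the other with the highest lower-of-2 score percentile. Alternatives fixed before the data were examined were the genotype field grouping, lists shortened to the 38142 summits of the shortest list, a score of at least 10, numbered autosomes only, joining distances of 100 and 1000 bp, and leaving out each library. Joining and counting were tested on simulated lists of the same lengths over 82899 regions, in which counts of all-library and pair-only regions were recovered with an error of at most 0.463%. The simulated summits were placed close to regions already joined, so that error does not cover a peak whose summits lie over 250 bp apart. The spread of region strength in the simulated lists was first 4 and was then set to 2.5, chosen because it came near the observed pair-only counts and the observed number of regions in all 4 libraries; both were kept. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.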

Results

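FAIRE-seq summits were compared between the dentate gyrus of wild-type mice and of mice lacking Mbd1, which encodes a protein that binds methylated CpG sites and is linked to gene silencing. The dentate gyrus is a part of the hippocampus that holds granule neurons and, in the adult mouse, neural stem cells. The design asked which active regulatory elements differ between the genotypes. Each group had 2 libraries by title. The libraries titled WT 1 and WT 2 held 38142 and 46651 summits, and those titled Mbd1 KO 1 and Mbd1 KO 2 held 56382 and 49671. The genotype field contradicts the titles for WT 1 and Mbd1 KO 2, so the main comparisons are given under both groupings and libraries are named by title. The Mbd1 gene itself, which would check the labels in a knockout design, was not analysed here because no mm9 annotation was used. Read depth is not known from the summit lists.

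The 4 libraries shared a core of regions with high scores. Input control and read filters are not known, so a high score shared by all 4 may not mark open chromatin. Joining summits within 250 bp gave 82899 regions, of which 26592 (32.1%) were called in all 4 libraries, 8313 (10.03%) in 3, 11425 (13.8%) in 2 and 36569 (44.1%) in 1 only. The 100 summits with the highest score of each library all lay in regions called in all 4 libraries, and of the 1000 highest between 995 and 998 did. The highest score in every library was at a region on chromosome 9 (35112979 to 35112992), with scores from 289 to 321. Regions on chromosome 12 (98299806 to 98299820, and 3109975 to 3109992) held ranks 2 and 3 in each library. The next in the order of shared strength were on chromosome 17 (36621755 to 36621772), ranked 4 to 6, and on chromosome 9 (123371133 to 123371142), ranked 5 to 9. Recurrence fell with the score. In the top decile of each list by score, 99.4% to 99.5% of summits lay in regions of all 4 libraries. In the lowest decile this share was 17.3% for WT 1, 5.29% for WT 2, 1.80% for Mbd1 KO 1 and 4.15% for Mbd1 KO 2.

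**Figure D1:**
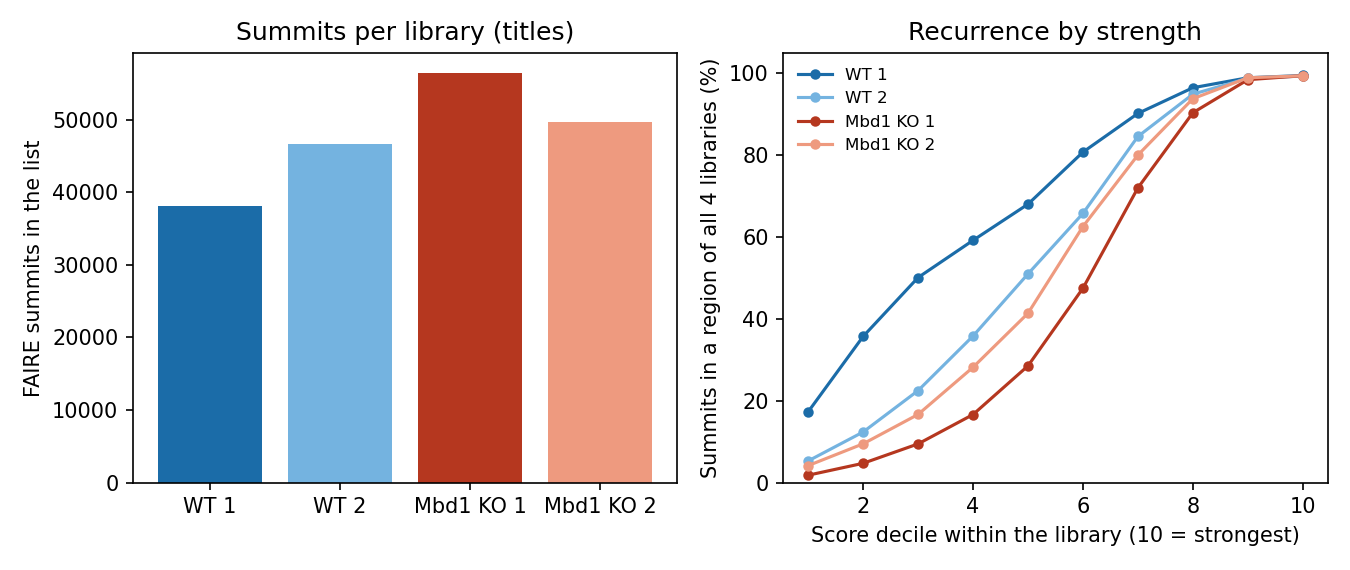
Left, the number of summits in the list of each library, by title. Right, for each decile of a library's summits by score (10 is the strongest), the percentage that lay in a region called in all 4 libraries; the 4 lines meet above 99% in the strongest decile and part in the weakest, where WT 1, the shortest list, is at 17.3% and Mbd1 KO 1, the longest, at 1.80%.

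Shared regions were densest in a few short stretches. The window of 50 kb with the most regions of all 4 libraries was on chromosome 9 (3000001 to 3050000), with 28 such regions and between 30 and 32 summits per library. It was followed by chromosome 11 (3050001 to 3100000) with 24 regions, chromosome Y (2850001 to 2900000) with 21 and chromosome 8 (19900001 to 19950000) with 16. On chromosome 11 the window held 27 and 32 summits in WT 1 and WT 2 against 25 and 31 in Mbd1 KO 1 and Mbd1 KO 2. With input control and read filters unknown, such dense windows may not mark open chromatin either. Across the genome the median spacing of neighbouring summits was 30.7 ± 3.31 kb in the libraries titled WT and 25.5 ± 1.24 kb in those titled Mbd1 KO (SD, n = 2 each, exact permutation p = 0.33, two-sided, the smallest this design allows).

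By title, the Mbd1 KO libraries held more summits than the WT libraries, and the summits with a score of at least 10 made up 3004 of the mean difference of 10630. The lists averaged 53027 ± 4745 summits against 42397 ± 6017 (SD, n = 2 each), a ratio of 1.25 (exact permutation p = 0.33, two-sided, the smallest this design allows). Among summits with a score of at least 10 the averages were 25085 ± 1131 and 22082 ± 412, a ratio of 1.14 (exact permutation p = 0.33). There were 3377 regions called in both Mbd1 KO libraries and neither WT library, and 808 with the opposite pattern. These regions were weak: the lower of the 2 score percentiles had a median of 20.02 in the first class and 17.2 in the second, against a median lowest percentile of 56.8 for regions of all 4 libraries. In lists shortened to equal length the numbers became 1450 and 1149.

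**Figure D2:**
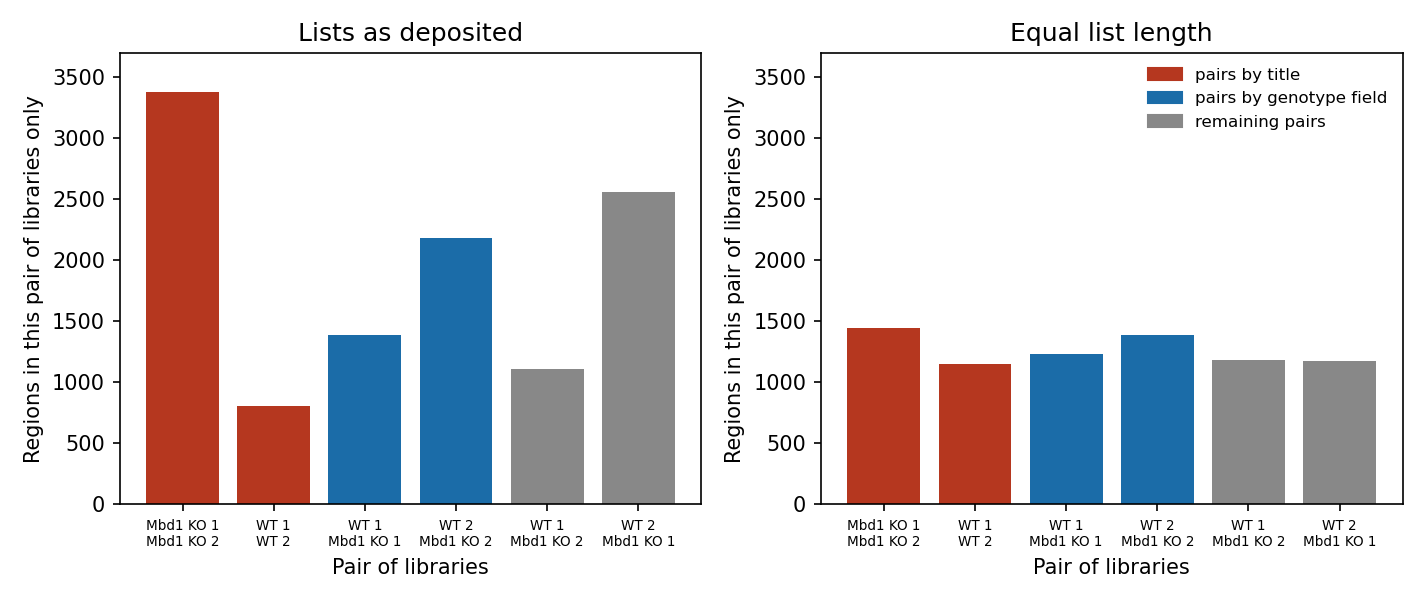
Number of regions called in exactly 1 pair of the 4 libraries, for each of the 6 pairs, with the lists as deposited (left) and shortened to the 38142 strongest summits each (right). Bars are coloured by the split a pair belongs to; the 3377 regions of the titled Mbd1 KO pair stand above the 808 of the titled WT pair on the left, and at equal length all 6 pairs lie between 1149 and 1450.

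The strongest regions specific to a titled group each had a summit of the other group within 1000 bp. For the pair titled Mbd1 KO these were on chromosome 16 (38089013 to 38089087), chromosome 7 (51560325 to 51560370), chromosome 17 (39984839 to 39984856), chromosome 11 (27914541 to 27914542) and chromosome 4 (117852309 to 117852323), with scores from 26.3 to 73.2. The nearest summit of a WT library was 281, 304, 987, 337 and 376 bp away. For the pair titled WT they were on chromosome 16 (38089368 to 38089374), chromosome 17 (39983849 to 39983852) and 3 times on chromosome 1 (120285896 to 120285939, 94831253 to 94831263 and 173193056 to 173193064), with scores from 25.4 to 59.6. The nearest Mbd1 KO summit was 281, 877, 336, 316 and 343 bp away. The first region of each direction lies at the same place on chromosome 16. All 6 Mbd1 KO regions and all 7 WT regions above the 80th percentile had a summit of the other group within 1000 bp. Over all strengths this was so for 289 of the 3377 (8.56%) and 133 of the 808 (16.5%).

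With regions that had a summit of the other group within 1000 bp left out, a choice made after the data were seen, the strongest Mbd1 KO regions were on chromosome 12 (72015531 to 72015539), chromosome 18 (37925558 to 37925571), chromosome 17 (73586997 to 73587028), chromosome 18 again (37179700 to 37179707) and chromosome 13 (45755435 to 45755452). Their lower score percentiles ran from 76.8 down to 68.2. The strongest WT regions chosen in this way were on chromosome 18 (74196979 to 74196989), chromosome 6 (120786192 to 120786195), chromosome 1 (182741241 to 182741245), chromosome 7 (130644136 to 130644143) and chromosome 13 (101421011 to 101421042), with percentiles from 70.3 down to 58.8. Single regions were not tested.

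Libraries of 1 titled group overlapped about as much as libraries of different titled groups. The Jaccard index was 0.545 between the WT libraries and 0.510 between the Mbd1 KO libraries. Between the groups it was 0.498 for WT 1 with Mbd1 KO 1, 0.553 for WT 1 with Mbd1 KO 2, 0.491 for WT 2 with Mbd1 KO 1 and 0.538 for WT 2 with Mbd1 KO 2. The mean within the groups exceeded the mean between them by 0.0075. The same difference was −0.0069 for the grouping of the genotype field and −0.00056 for the remaining split, and 3 splits allow no share below 0.33. At equal list length the index was highest between the Mbd1 KO libraries (0.648) and lowest between the WT libraries (0.600), and the difference for the titles was 0.0022. The pairs of the genotype field had 0.613 (WT 1 with Mbd1 KO 1) and 0.635 (WT 2 with Mbd1 KO 2). Those of the remaining split had 0.622 (WT 1 with Mbd1 KO 2) and 0.617 (WT 2 with Mbd1 KO 1). The field pairs thus overlapped about as much as the titled pairs there. Over the 26592 regions of all 4 libraries, the score percentiles correlated with Spearman's rho from 0.808 (WT 1 with WT 2) to 0.841 (Mbd1 KO 1 with Mbd1 KO 2). The mean rho within pairs was 0.834 for the genotype field, 0.825 for the titles and 0.822 for the remaining split. These are correlations across regions, which are not independent replicates.

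By the genotype field the direction of the summit numbers turned. The libraries with the field Mbd1 KO (titled WT 1 and Mbd1 KO 1) averaged 47262 ± 12898 summits and those with the field WT (titled WT 2 and Mbd1 KO 2) 48161 ± 2135 (SD, n = 2 each), a ratio of 0.981 (exact permutation p = 1, two-sided). Among summits with a score of at least 10 the ratio was 0.955 (exact permutation p = 0.667), and the median spacing was 28.8 ± 5.97 kb against 27.3 ± 1.42 kb (exact permutation p = 1). There were 1386 regions specific to the first pair and 2182 specific to the second. The strongest were neighbouring summits on chromosome 9, at 21760505 in the first pair and at 21760138 to 21760168 in the second, 337 bp apart. A region on chromosome 8 (56207721 to 56207724) in the second pair had no summit of the other pair within 1000 bp and lay 1120 bp from the nearest one. In the 2 libraries whose labels agree, 22496 regions were called in Mbd1 KO 1 and not in WT 2, 12758 in WT 2 and not in Mbd1 KO 1, and 33874 in both; with 1 library per group these numbers have no replicate check.

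Weakly recurring regions were spread over the chromosomes differently from the shared core. Chromosome 11 held 6.28% of the regions called in all 4 libraries but 4.46% of those called in 2 (odds ratio 0.70, Fisher's exact test over regions, adjusted p = 2.53e-11), and chromosomes 7 and 9 were also lower, at 4.47% against 5.43% and 4.19% against 5.06%. Chromosome 14 held 5.90% against 4.24% (odds ratio 1.42, Fisher's exact test, adjusted p = 9.18e-11), and chromosomes 1 and 3 were also higher, at 8.47% against 7.58% and 7.16% against 6.04%. These 6 of 22 chromosomes, the mitochondrial one included, passed the Benjamini-Hochberg adjustment. Between regions specific to the titled Mbd1 KO pair and those specific to the titled WT pair, 0 of 22 passed, and 1 had an unadjusted Fisher p under 0.05, chromosome 2 with 8.05% against 5.94% (p = 0.0463, adjusted p = 0.756). A permutation test of the distributions over all chromosomes gave p = 0.831. Between the pairs of the genotype field 0 of 22 passed, and the permutation test gave p = 0.343.

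**Figure D3:**
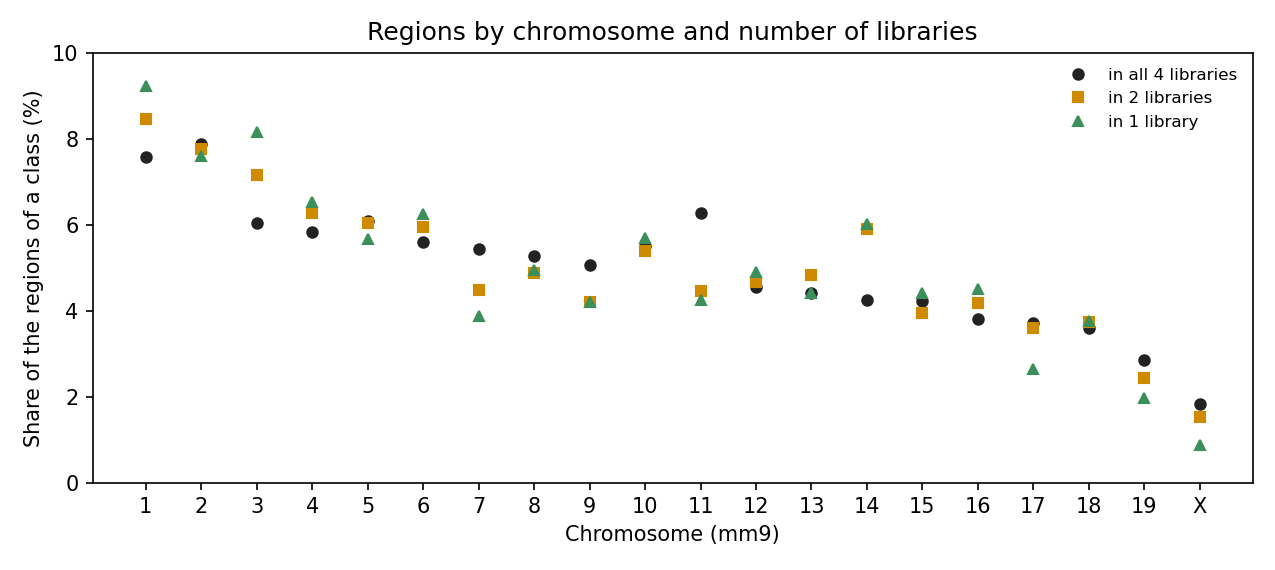
Share of regions on each autosome and on chromosome X, in percent of all regions of a class, for regions called in all 4 libraries (circles), in 2 (squares) and in 1 (triangles). Chromosomes 7, 9 and 11 lie lower for regions of 2 libraries than for those of all 4, and chromosomes 1, 3 and 14 lie higher.

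Chromosome X held 1.59 ± 0.109% of the summits of the libraries titled Mbd1 KO and 1.71 ± 0.108% of those titled WT (SD, n = 2 each, exact permutation p = 0.667, two-sided). The difference of −0.123 percentage points was −0.00078 with the groups of the genotype field, −0.018 among summits with a score of at least 10, and between −0.046 and −0.200 with 1 library left out. With the 38142 strongest summits of each library the order turned, with 1.91 ± 0.033% against 1.84 ± 0.070% (exact permutation p = 0.33). With the 10000 strongest, a setting added after the data were seen, it did not turn, and the difference was −0.135 percentage points. Every library had between 69 and 75 summits on chromosome Y and 2 on the mitochondrial chromosome. Regions specific to the titled Mbd1 KO pair lay a median of 29.3 kb from the nearest region of all 4 libraries (quartiles 10.8 and 71.1 kb), and those specific to the WT pair 27.6 kb (quartiles 8.35 and 59.4 kb). The mean log10 distance differed by 0.097 (permutation test over regions, p = 0.00012). Regions are not replicates, so that p-value describes these libraries only. With the pairs of the genotype field the medians were 26.1 kb for Mbd1 KO and 27.9 kb for WT, and the mean log10 distance differed by −0.010 (permutation test over regions, p = 0.654). Neighbouring regions of all 4 libraries lay a median of 21.6 kb apart, and regions of 1 library only 36.2 kb from the nearest of them.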

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

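With the groups of the genotype field, the ratio of summit numbers turned from 1.25 to 0.981, the within-minus-between overlap from 0.0075 to −0.0069, and the regions specific to the Mbd1 KO and WT pairs changed from 3377 and 808 to 1386 and 2182. These values are for the lists as deposited and follow from the exchange of WT 1 and Mbd1 KO 2 between the groups. At equal list length the pairs of the genotype field overlapped about as much as the titled pairs. At a score of at least 10 the region counts were 1349 for Mbd1 KO, 365 for WT and 16046 for all 4 libraries. With the 38142 strongest summits of each library the Mbd1 KO count fell to 1450 and the WT count rose to 1149, and the chromosome X difference (Mbd1 KO minus WT) turned from −0.123 to 0.0787 percentage points; equal lengths fix the ratio of summit numbers at 1, so it has no value there. With the 10000 strongest, a setting added after the data were seen, the counts were 343, 332 and 6635, and the overlap difference turned to −0.0023; the cause was not tested. The chromosome X difference kept its direction in that setting, at −0.135 percentage points. In the 2 libraries whose labels agree, also added later, the Mbd1 KO and WT counts were 22496 and 12758, because 1 library per group leaves fewer conditions to meet. Leaving out 1 library, the Mbd1 KO count ran from 5619 (without WT 1) to 18836 (without Mbd1 KO 2), and the WT count from 2017 (without Mbd1 KO 1) to 9233 (without WT 1). The overlap difference ran from −0.0158 (without WT 2) to 0.0501 (without Mbd1 KO 2) and was −0.0047 without WT 1, so its direction rests on single libraries. The ratio of summit numbers stayed above 1 in these 4 settings, from 1.14 (without WT 1) to 1.39 (without WT 2). Joining distances of 100 and 1000 bp and autosomes alone changed no direction, and no count by over 1.5 times. With a replicate block, added after the data were seen, the ratio of summit numbers was 1.25 (1.48 in pair 1 and 1.06 in pair 2), and spacing differed by −8.44 and −2.01 kb; each gave an exact sign-flip permutation p of 0.5, the smallest that 2 pairs allow. The labels do not say what a number marks, deviations of same-numbered libraries from their group means correlated at 0.013 over the 26592 shared regions, and the numbers pair the libraries as the genotype field groups them. The promoter alternatives were not run, since no mm9 annotation was used. The exact permutation test cannot pass 0.05 with 2 libraries against 2, and list length cannot be corrected for depth.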

Other observations

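All tests in this part were chosen after the results were seen, except the permutation test of the summit numbers, which was planned. Mbd1 KO 1 alone held 15427 regions found in no other library, 27.4% of its regions, against 9.15% for WT 1, 18.01% for WT 2 and 18.7% for Mbd1 KO 2. In windows of 5 Mb, the number of regions found in 1 library only correlated weakly with the number shared by all 4, with Spearman's rho of 0.137 for WT 1, −0.016 for WT 2, −0.128 for Mbd1 KO 1 and 0.059 for Mbd1 KO 2 (504 windows, which are not independent replicates).

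The excess of regions specific to the titled Mbd1 KO pair over the titled WT pair, 3377 against 808, may come from how readily each library called any region. If each library has its own call rate, the ratio can be predicted from other regions. Those called in exactly 3 libraries predict 5.13 and those called in exactly 1 predict 4.87, while the observed ratio was 4.18 (95% counting interval 3.87 to 4.51), below both. The prediction is rough: for the remaining split the observed ratio was 0.434 (0.405 to 0.466) against 0.674 from regions called in 3 libraries and 0.249 from those called in 1, and for the genotype field 0.635 (0.594 to 0.679) against 0.581 and 0.693. A set of regions following the titles stays open. The geometric mean of the 2 pair-only counts was devised after the counts were seen. Where libraries differ only in call rate, it is equal for the 3 splits, though its level changes with list length. The ratios above depart from what such libraries predict, and the simulated lists assume such libraries. Gaps between the splits therefore do not decide whether regions follow a label. The geometric mean was 1652 ± 32 (SE, counting error only) for the titles, 1739 ± 30 for the genotype field and 1687 ± 30 for the remaining split, and in simulated lists 250 regions gained and 250 lost raised it from 1683 to 2060. The spread of region strength in that simulation was chosen to come near the observed level. With the spread tried first the same change raised the geometric mean from 928 to 1395. Every simulated change was complete, called in both libraries of a titled group and in neither of the other, with equal numbers each way. Partial changes and changes in a single direction were not simulated, so the rise does not show how they would appear. In the lists as deposited the titles were not above the other splits, nor below either by over 2 SE of the difference. At equal list length they reached 1291 ± 25 against 1181 ± 24 for the remaining split and 1309 ± 26 for the genotype field. At a score of at least 10 they reached 702 ± 21 against 769 ± 20 for the genotype field. They were the lowest of the 3 splits in 7 of 27 settings, which reuse the same lists and are not independent. Deeper sequencing and wider accessibility across the genome in the libraries titled Mbd1 KO cannot be told apart, because read depth is not known. The summit numbers gave an exact permutation p of 0.33, the smallest this design allows, and that test cannot separate them.

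The split that follows the genotype field, and equally the replicate numbers, had the highest geometric mean in all 27 combinations of list length, score minimum and joining distance tried, and led both others by over 2 SE of the difference in 21 of them. The other 6 were the lists as deposited and those of 38142 summits: at 38142 it was 1309 ± 26 (SE, counting error only) against 1291 ± 25 for the titles with summits joined over 250 bp and 1210 ± 25 against 1202 ± 25 over 1000 bp. Among the 10000 strongest summits of each library it was 412 ± 14 (SE, counting error only) against 337 ± 13 for the titles and 298 ± 12 for the remaining split, and among the 2000 strongest 103 ± 7.18 against 58.8 ± 5.43 and 54.9 ± 5.24. Most of the regions counted are not ones that the other libraries lack: of the 825 regions counted for the genotype field among the 10000 strongest, 804 (97.5%) had a summit of both other libraries within 250 bp in the full lists. The share was alike for the titles, 656 of 675 (97.2%), and for the remaining split, 584 of 597 (97.8%). How far below the cut the summits of the other libraries ranked was not examined. Summits placed at different points of one peak are argued against as the source among the 10000 strongest, where joining over 1000 bp left 395 ± 14 against 320 ± 13. In the lists as deposited this could not be tested, since the lead was within its error before that joining as well as after it (1615 ± 29 against 1587 ± 30 for the remaining split). A different sex of the mice in the pairs is argued against by the chromosome X share at equal list length, whose ratio between the pairs was 0.986; that of chromosome Y was 0.992. Other measures of the genotype field split were mixed in the lists as deposited. Its mean rho within pairs was the highest of the 3 splits, at 0.834. Its within-minus-between overlap was the lowest of the 3, at −0.0069. Genotype as the field gives it and a preparation shared by replicate number cannot be told apart, because both part the libraries alike and 3 splits allow no share below 0.33.

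Chromosome 18 was looked at before any scan because it carries Mbd1 in the GRCm38 gene table, with counts above 5 percentile limits. The first scan statistic, the largest count in any 2 Mb window, did not single it out: the window with the most regions of the titled Mbd1 KO pair was on chromosome 18 with summits joined over 250 bp (13 regions, permutation scan p = 0.988) and on chromosome 7 over 1000 bp (p = 0.902), and that of the titled WT pair was on chromosome 4 (146000001 to 148000000, 10 regions, permutation scan p = 0.0144, adjusted p = 0.0864 over 6 classes) and on chromosome 1 (p = 0.833). A second statistic, the smallest binomial tail of a window, and a class above the 50th percentile were chosen after that, and with them chromosome 18 held the leading windows of both titled directions in some scans. At 36000001 to 38000000, 13 of 16 regions called in exactly 2 libraries were specific to the titled Mbd1 KO pair and 1 to the titled WT pair (permutation scan p = 0.0125 over 2000 permutations; with summits joined over 1000 bp it was 11 of 14, scan p = 0.196). At 74000001 to 76000000, 3 of 5 such regions above the 50th percentile were specific to the titled WT pair (permutation scan p = 0.0055 with summits joined over 1000 bp and 0.027 over 250 bp). Neither passed adjustment over the 24 scans, where the smallest value for the titles was 0.132 and which does not cover the first statistic or the limits looked at, so chance clustering may account for both. A candidate explanation is a segment of chromosome 18 that differs with the titles, such as sequence linked to the targeted allele: that chromosome held 178 of the 4185 regions specific to a titled pair (4.25%) and 248 of 7240 of the other splits (3.43%; Fisher's exact test over regions, p = 0.0274, adjusted p = 0.258 over 21 chromosomes). That count includes the windows already picked out, and chromosomes 3 (odds ratio 0.82, Fisher p = 0.0116) and 16 (odds ratio 0.81, Fisher p = 0.0368) departed about as much in the other direction. Chromosome 18 as a whole thus does not stand apart. A share over the whole chromosome cannot judge a local segment, and the position of Mbd1 in mm9 was not used, so the explanation stays open.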
